A study of Danio rerio with 6 samples.

How the data were processed

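Poly-A-selected RNA from whole retinas of 6-month-old zebrafish (AB* background) was sequenced in 6 samples, 3 wild-type and 3 homozygous for the stl628 allele of thrb, with the mutants taken from the same clutches. Per the labels' protocols, a sample combined 2 retinas of a male and 2 of a female, every RNA integrity number was above 8.7, and libraries were amplified for 12 cycles. The library protocol in the labels names no step that marks strand, so reads of overlapping genes on opposite strands cannot be told apart.

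The authors' processing notes, as submitted, name cutadapt 1.9.1, STAR 2.7.2b, HTSeq 0.9.1, DESeq2 1.18.1, R 3.4.3 and the genome build danRer10, without their order or settings. The annotation and any expression filter are not given in the sources used here. The data used are 1 table that the authors deposited, with 9211 gene rows and no values per sample. For each gene the authors deposited the mean normalized count of each genotype, a signal that is the count divided by a size factor and averaged over the samples, and the mean over both genotypes. The deposited log2 fold change (mutant over wild-type) and its standard error come from a DESeq2 fit that the authors made, per the file headers and the submitters' processing notes. The direction was checked on the values: the fold change differs from the log2 ratio of the deposited group means by at most 0.030. The deposited statistic, a score, equals the excess of the absolute log2 fold change over 1 divided by its standard error, with 0 for smaller changes. The deposited p-value therefore asks whether a gene changed by more than 2-fold, and it is 1 for every gene below that size. Only 36 genes have a deposited p-value below 1.

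Among the rows, the larger of the group means is never below 50.04. The deposited adjusted p-values follow from an adjustment over 13700 genes, a number that gives whole ranks to pacsin2 and rassf6, the listed genes whose values are finely given and whose adjusted p no other listed gene shares. By that adjustment pacsin2, the 8th gene by p-value in the rows, had rank 13, so 5 genes with smaller p-values are not analysed here. The adjusted p of si:busm1-57f23.1 needs at least 9 genes at or below it, 7 of them listed, so at least 2 of the 5 passed the authors' test. In 10 rows the gene name has been turned into a calendar date, and these rows cannot be assigned to a gene. Read depth per library is unknown, since the table holds no counts. The group means sum to 10849262 normalized counts in wild-type and 10700117 in mutant retina over the listed genes. Precision was therefore taken from the deposited standard errors, whose median is 0.14 on the log2 scale (5th to 95th percentile, 0.092 to 0.28).

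The result planned for a table of this kind was the number of genes with a deposited adjusted p under 0.05. Because that test ignores changes below 2-fold, a test against no change was added after the data were seen: the deposited log2 fold change divided by its standard error, compared with the normal distribution, two-sided, with Benjamini-Hochberg adjustment over the 9211 genes. Unless stated otherwise, "rose", "fell" and adjusted p below refer to this added Wald test. The central spread of its statistic (interquartile range scaled to a normal distribution) was 0.94, where 1 is the spread without any change. The 95% intervals are 1.96 standard errors wide on either side, from the same normal distribution. Values of one standard error assume that the authors' model describes the spread between the 3 samples of a group.

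Before the data were examined, 25 gene lists of retinal cell types, contaminating tissues and pathways were fixed, along with the rule for naming genes. List members absent under the fixed symbol were looked up through RefSeq synonyms. The 20 lists with at least 3 measured members were tested with cameraPR (limma 3.58.1, R 4.3.3), which asks whether a list's statistics are shifted against all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The statistic was the log2 fold change over its standard error, because the deposited statistic is 0 for nearly all genes. An estimated correlation needs values per sample and could not be used, so 0.05 was tried as a second preset value. As thrb is the mutated gene, the lists were also tested with thrb left out, a choice made after the data were seen. The named genes were thrb, all visual opsins, cyp27c1, the 8 genes of each direction with the largest fold change among those past the threshold with a mean count of at least 100 and a gene symbol that is not a clone name, the 5 of each direction with the largest statistic, and up to 4 past the threshold in each list, or the 2 most abundant where none passed. The rule was applied to both tests.

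The list test needed more choices after the data were seen: a glycolysis list, a clustered protocadherin 2 list and the melanin members of the pigment list were drawn up from genes that had changed. Paralogs were compared by the difference of their log2 fold changes over the combined standard error, which treats the 2 estimates as independent, adjusted over 57 pairs. These are all pairs of measured genes whose symbols share a stem and end in a and b, with at least 1 member in a fixed list; the rule was set after the data were seen. Gene order came from RefSeq annotation of the GRCz12tu assembly, which is not the build used by the authors, and placed 9130 of the genes. It served only to tell which genes lie on the chromosome of thrb or within 5, 10 or 20 Mb of it, and no coordinates are given. Calls there, with thrb left out, were compared with calls elsewhere by a two-sided Fisher exact test. The tests were checked on simulated fold changes with the deposited standard errors over 9211 genes. The test against no change recovered 51% of genes changed by 0.5 and 93% of those changed by 1 on the log2 scale. The test against 2-fold recovered 0% of genes changed by exactly 1 and 99% of those changed by 2.5. In the list test, a planted list of 15 genes shifted by 0.3 was found and none of the 19 unshifted lists was called. The simulated errors were normal and independent between genes. These checks therefore cannot test the choice of the normal distribution, or the effect of correlation between members of a list. Alternatives changed the threshold, the set of adjusted genes, the count minimum (10 or 100), the reference distribution (t with 4 degrees of freedom), the null size (1.5-fold), the centring of the fold changes and the settings of the list test. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.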

Results

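The retinal transcriptome of adult zebrafish lacking thrb, the gene for the thyroid hormone receptor beta, was compared with that of wild-type fish from the same clutches. Each genotype was represented by 3 samples, and each sample pooled retinas of both sexes. Zebrafish retinas hold rods and 4 spectral types of cone, the red, green, blue and ultraviolet cones, each marked by its own opsin genes. The comparison asks which transcripts differ in the adult retina of these mutants, and how the transcripts of the photoreceptor types differ. The mutants were homozygous for the allele and only adults were sampled. Dependence on the receptor in the mature retina therefore cannot be told from an effect during development. Fewer or absent red cones would lower their transcripts, as would lower expression per cell, and whole-retina counts do not separate these. The authors' deposited table gives 9211 genes with a median mean normalized count of 356. Values below are group means and fold changes with standard errors from that table. The p-values of Wald tests rest on those standard errors, and so only on the spread between the pooled samples as the authors' model estimated it. Those of the list, Fisher exact and permutation tests take genes as units and do not measure spread between samples.

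The red opsin transcripts were nearly absent from the mutant retina. In the authors' deposited table, opn1lw2, a red cone opsin, had a mean normalized count of 61.1 in mutants against 41322 in wild-type, 687-fold lower (log2 fold change -9.42, SE 0.16). The other red opsin, opn1lw1, stood at 177 against 51643 in the authors' deposited table, 292-fold lower (log2 fold change -8.19, SE 0.40). Transcripts of thrb itself were 8.03-fold lower, at 413 against 3301 (log2 fold change -3.01, SE 0.13, in the authors' deposited table), which leaves 12.4% of the wild-type level. The microRNA gene mir726, which directly neighbours opn1lw1 in gene order, fell from 256 to 7.96 in the authors' deposited table (log2 fold change -5.0, SE 0.35). The RNA was poly-A-selected, so these counts need not reflect the mature microRNA, and reads from the neighbouring opsin transcript were not excluded. The fold change of opn1lw2 was larger than that of opn1lw1 by 1.24 (SE 0.44), and reads of such paralogs cannot always be assigned to one of them. The 3 genes fixed in advance as red cone genes, the 2 red opsins and thrb, all fell, with a median of -8.19, and the same 3 when adjusted over the list alone. As thrb is the mutated gene, its fall is no separate evidence about red cones, and without it the list was too short to test.

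Among the listed genes, 7 passed the authors' own test for a change beyond 2-fold, 6 lower and 1 higher in the mutant, at a deposited adjusted p under 0.05. The adjusted p-values imply that at least 2 more genes passed that are not among the listed ones and not analysed here. In the authors' deposited table the adjusted p was 4.18e-67 for opn1lw1, 2.89e-48 for thrb and 2.00e-27 for mir726, and it was given as 0 for opn1lw2. The remaining listed genes that fell were mhc1uba, a major histocompatibility complex class I gene, and the uncharacterised si:busm1-57f23.1. In the authors' deposited table mhc1uba went from 290 to 38.6 (log2 fold change -2.94, SE 0.23, adjusted p = 2.03e-14) and si:busm1-57f23.1 from 3318 to 302 (-3.46, SE 0.51, adjusted p = 0.0027). The listed gene that rose was serinc2, of the serine incorporator family, from 58.6 to 291, a 4.96-fold increase in the authors' deposited table (log2 fold change 2.31, SE 0.19, adjusted p = 1.69e-08). Of the listed genes, 32 were more than 2-fold lower and 4 more than 2-fold higher by point estimate, without regard to error. The standard errors treat the 3 samples of a group through the authors' model, and against a t distribution with 4 degrees of freedom only opn1lw2 passed.

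**Figure D1:**
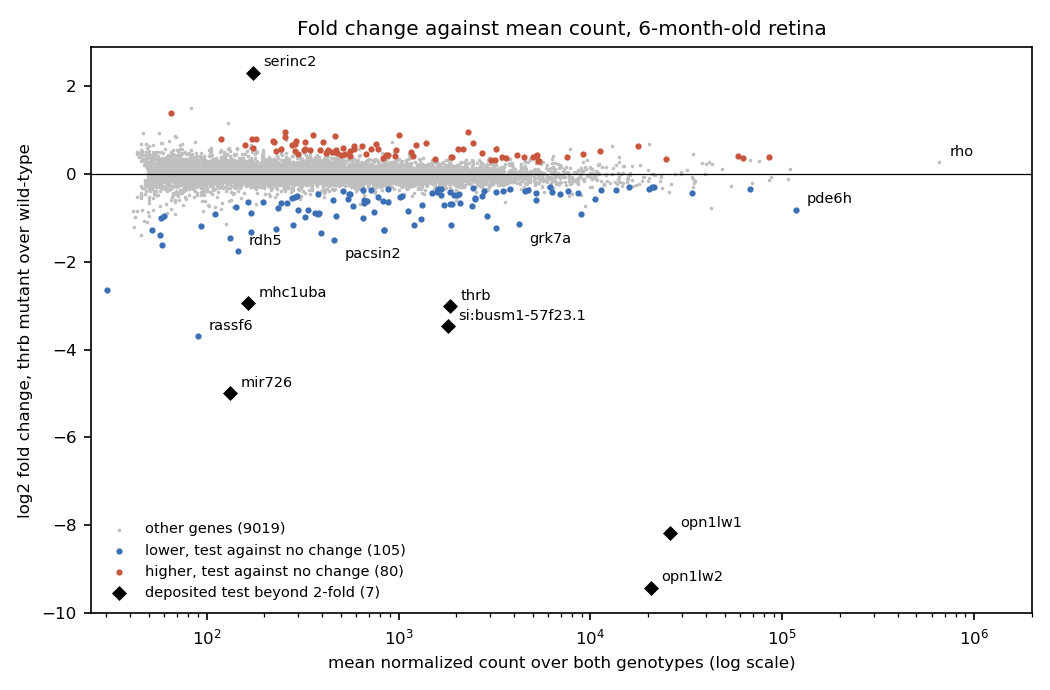
Log2 fold change of the thrb mutant over wild-type (vertical axis) against the mean normalized count over both genotypes (horizontal axis, log scale), 1 point per gene. Black diamonds are the 7 listed genes past the authors' test for a change beyond 2-fold, blue and red points the other genes that fell or rose in the test against no change, and the red opsins lie lowest, at -8.19 and -9.42.

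Against no change, 192 genes differed between the genotypes, 111 lower and 81 higher, with a median absolute log2 fold change of 0.57. The count depends on the normal distribution as reference: against a t distribution with 4 degrees of freedom it was 1 (opn1lw2), and 41 of 68 genes named in this text by a fixed rule lost their call. Of these, 91 had changed by at least 1.5-fold, 63 of them downward. Besides the genes already named, and among genes with a symbol and a mean count of at least 100, the largest falls were those of rdh5, a retinol dehydrogenase of the visual cycle (log2 fold change -1.75, SE 0.21), pacsin2, a membrane-bending protein of endocytosis (-1.49, SE 0.13), and relt, of the tumour necrosis factor receptor family (-1.47, SE 0.21), all as given in the authors' deposited table. Under the same limits the largest rises after serinc2 were those of fbxl6 (0.97, SE 0.15), the transcriptional repressor zbtb20 (0.96, SE 0.14), and the clustered protocadherins pcdh2ab12 (0.88, SE 0.13) and pcdh2ab11 (0.85, SE 0.18), again from the authors' deposited table. They were followed in the authors' deposited table by cd82b (0.80, SE 0.20), lingo2b (0.79, SE 0.22) and hs3st4 (0.79, SE 0.17), while ube2d4 (0.72, SE 0.11) and fam65b (0.65, SE 0.10) had some of the largest statistics. The adjusted p of these genes from the Wald test ran from 0.019 for lingo2b to 1.67e-28 for pacsin2. Members of the protocadherin cluster share sequence, and their separate counts are uncertain.

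The opsins of the other photoreceptors were modestly higher or did not pass the test. The green opsin opn1mw2 rose 1.34-fold (log2 fold change 0.42, SE 0.11, adjusted p = 0.0165) and the blue opsin opn1sw2 1.29-fold (0.37, SE 0.11, adjusted p = 0.035, Wald test on the authors' deposited table), though opn1sw2 did not pass when adjusted over the 13700 genes that the deposited values imply (adjusted p = 0.052). The ultraviolet opsin opn1sw1 was 1.25-fold higher (log2 fold change 0.32, 95% interval 0.125 to 0.515) and the rod opsin rho 1.21-fold higher (0.27, interval 0.083 to 0.46), with adjusted p of 0.058 and 0.14 from the same test. Intervals for the remaining green opsins included 0, from -1.32 to 1.01 for opn1mw1, -0.31 to 1.68 for opn1mw3 and -0.11 to 0.48 for opn1mw4. Added together from the authors' deposited table, the 2 red opsins went from 92965 to 239 normalized counts, the 4 green opsins from 89606 to 116962 and the blue and ultraviolet opsins from 114446 to 145095. All cone opsins together stood at 88.3% of the wild-type sum, and cone opsins without the red ones at 128%. These sums carry no error, because the table holds no values per sample.

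**Figure D2:**
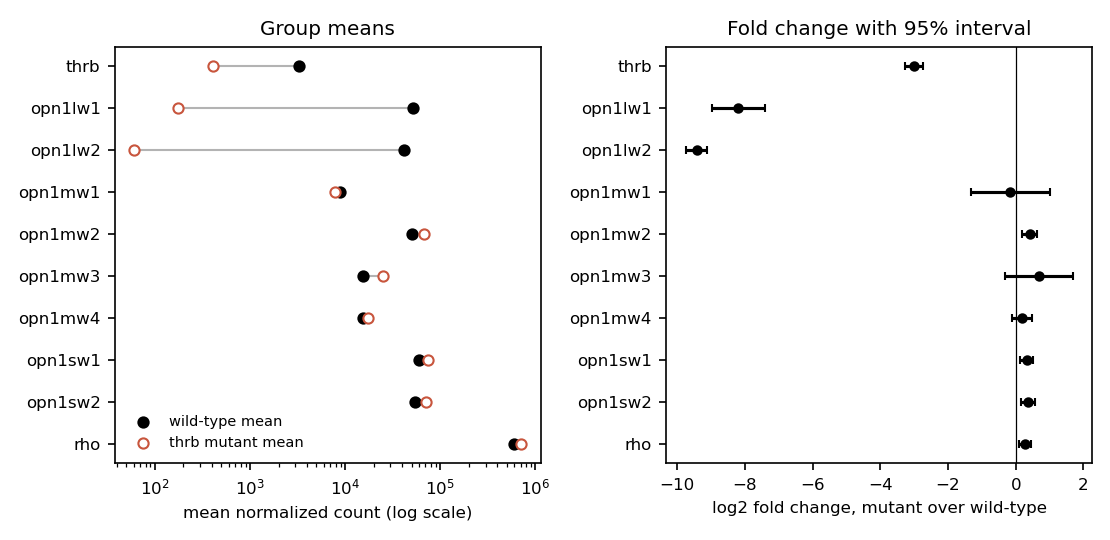
Left, mean normalized counts (log scale) of thrb and the visual opsins in wild-type (filled) and thrb mutant retina (open), as the authors averaged them. Right, log2 fold change of mutant over wild-type with 95% intervals from the deposited standard errors, where the 2 red opsins and thrb lie far below 0 and all others between -0.16 and 0.68.

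The list of genes shared by several cone types ranked low, with members that moved both ways. Of 20 measured pan-cone phototransduction genes, 4 fell, 1 rose and 15 did not pass, and the list ranked below all other genes (median log2 fold change -0.25, cameraPR adjusted p = 7.73e-10). The falls were those of grk7a, a cone opsin kinase (-1.14, SE 0.096), gngt2a, a cone transducin gamma subunit (-0.91, SE 0.14), pde6h, the inhibitory subunit of the cone phosphodiesterase (-0.81, SE 0.089), and rgs9a, which speeds transducin shut-off (-0.48, SE 0.11), as given in the authors' deposited table. The paralog grk7b rose in the authors' deposited table (0.63, SE 0.17), 1.76 apart from grk7a (SE 0.19, adjusted p = 7.83e-18, Wald test of the difference). The change of gngt2a was 0.91 below that of gngt2b (SE 0.20, adjusted p = 0.00011) in the same kind of test, while gnb3a and gnb3b did not differ detectably (0.10, SE 0.16, adjusted p = 0.87), nor did the cone arrestins arr3a and arr3b (-1.17, SE 0.46, adjusted p = 0.080). Of 57 pairs of measured paralogs named a and b with a member in a fixed list, 7 differed. Neither arrestin passed alone, with log2 fold changes of -0.76 (SE 0.30) and 0.41 (SE 0.35) in the authors' deposited table. The genes grk7b, gngt2b, arr3a, arr3b, gnb3a and gnb3b were singled out after their values were seen. Adjusted over the list alone, 5 pan-cone genes fell and 1 rose.

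Blue and ultraviolet cone genes and rod genes ranked above the rest. In the short-wavelength cone list of 6 genes, opn1sw2 and the transcription factor tbx2b rose (tbx2b, 0.33, SE 0.093 in the authors' deposited table), none fell, and the list's median was 0.32 (cameraPR adjusted p = 0.0075). The paralog tbx2a, also listed and named after its value was seen, stood at -0.19. It lay 0.52 below tbx2b (SE 0.13, adjusted p = 0.00069, Wald test of the difference). Adjusted over the list alone, 3 rose and 1 fell. The green cone list, 4 opsins, did not pass (median 0.30, cameraPR adjusted p = 0.069), with 1 member risen over all genes and 1 when adjusted over the list alone. Of 20 rod genes, 2 rose, none fell and 18 did not pass, with a median of 0.21 (cameraPR adjusted p = 5.8e-06). Those that rose were pde6g, the inhibitory subunit of the rod phosphodiesterase (0.38, SE 0.095), and the rod channel gene cnga1a, listed as si:dkey-22i16.2 (0.53, SE 0.091), in the authors' deposited table. Adjusted over the list alone, 8 rod genes rose and 1 fell.

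Among 21 photoreceptor transcription factors, 4 fell and 1 rose, and the list ranked below other genes (median -0.18, cameraPR adjusted p = 5.61e-05). The homeobox genes six7 (-0.59, SE 0.098) and rx2 (-0.68, SE 0.14), samd7, a photoreceptor repressor (-0.66, SE 0.12), and sall1a (-0.38, SE 0.11; named after its value was seen) fell in the authors' deposited table. The gene that rose was tbx2b. Adjusted over the list alone, 7 fell and 1 rose. In the list of thyroid hormone transport, metabolism and receptor genes, thrb and the corepressor ncor1 (-0.35, SE 0.10 in the authors' deposited table) fell and 16 of 18 did not pass, with a median of -0.045. The list's cameraPR adjusted p of 6.39e-05 rests on the mutated gene itself: with thrb left out, 1 of 17 fell and the adjusted p was 0.54. Adjusted over the list alone, 3 fell and 1 rose. The other thyroid hormone receptor listed, thraa, had a log2 fold change of 0.033 (SE 0.16) in the authors' deposited table, and it was looked up after the data were seen.

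Visual cycle genes ranked below the rest. Of 25 retinoid metabolism genes, 7 fell, none rose and 18 did not pass (median -0.094, cameraPR adjusted p = 4.57e-09), with the same 7 when adjusted over the list alone. Falls included rdh5, stra6, the retinol-binding protein receptor (-1.28, SE 0.14), rpe65a, the retinoid isomerohydrolase of the pigment epithelium (-1.16, SE 0.18), and rgrb, a retinal G protein-coupled receptor (-1.0, SE 0.12), in the authors' deposited table. Smaller falls, named after their values were seen, were those of rlbp1b (-0.49, SE 0.13), irbp (-0.43, SE 0.10) and rdh8b (-0.39, SE 0.11) in the authors' deposited table. The Müller glia paralog of rlbp1b, rlbp1a, differed from it by 0.58 (SE 0.16, adjusted p = 0.0020, Wald test of the difference). For cyp27c1, the enzyme that converts vitamin A1 to A2, the authors' deposited table gives 81.6 in mutants against 139 in wild-type (log2 fold change -0.76, 95% interval -1.39 to -0.13), and it did not pass after adjustment (Wald test adjusted p = 0.35).

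The 8 measured genes of pigment epithelium and melanin ranked low as a group, like the visual cycle genes, though 3 of them lay near 0. Here dct, pmela and tyrp1b, which serve melanin synthesis and the melanosome, and rpe65a fell, none rose, and the list's median was -0.73 (cameraPR adjusted p = 7.73e-10). In the authors' deposited table the log2 fold changes were -0.97 (SE 0.14) for dct, -0.96 (SE 0.15) for pmela and -0.88 (SE 0.16) for tyrp1b. Adjusted over the list alone 5 fell. The members mitfb, gpr143 and trpm1b did not pass, nor did pmelb (-0.57, SE 0.18), with values for the first 3 of 0.13, 0.02 and 0.06 and standard errors of 0.26, 0.24 and 0.11 in the authors' deposited table.

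**Figure D3:**
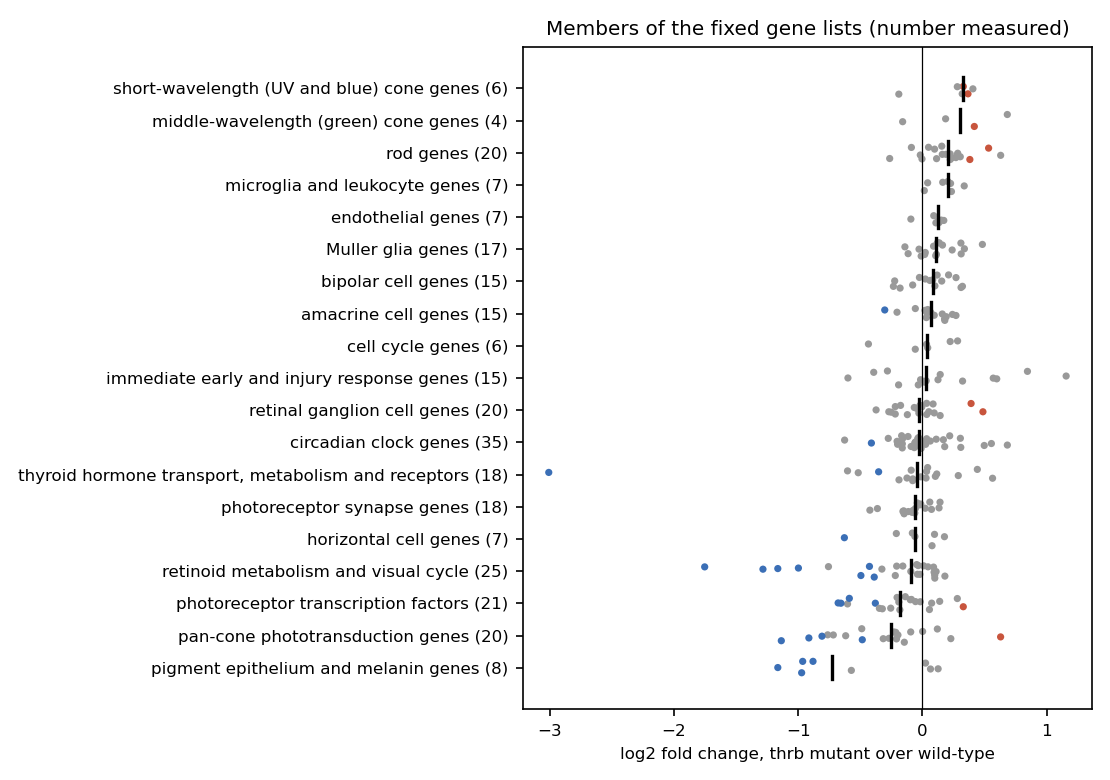
Log2 fold changes of the measured members of each tested list (points; blue fell, red rose, grey did not pass the test against no change) with the list median (black bar). The red cone list, with a median of -8.19, lies outside the range and is not drawn; pigment genes have the lowest median shown (-0.73) and short-wavelength cone genes the highest (0.32).

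Markers of the inner retina moved little. None of 15 bipolar genes passed (median 0.082, cameraPR adjusted p = 0.11), with cabp5a at 0.21 (SE 0.12) and gnao1a at 0.32 (SE 0.11) in the authors' deposited table. Of 7 horizontal cell genes 1 fell, lhx1a (-0.63, SE 0.18), and of 15 amacrine genes 1 fell, gad1b, a GABA-synthesising enzyme (-0.30, SE 0.086), in the authors' deposited table; the lists had adjusted p of 0.78 and 0.10 from cameraPR. Adjusted over 13700 genes, lhx1a (Wald test adjusted p = 0.055) and the ganglion cell gene elavl4 (0.072) did not pass. Of 20 ganglion cell genes 2 rose, the neuronal RNA-binding proteins elavl3 (0.49, SE 0.13) and elavl4 (0.39, SE 0.12) in the authors' deposited table, while the list did not shift detectably (median -0.024, upward by cameraPR, adjusted p = 0.80). None of 17 Müller glia genes passed, the list median was 0.11 (cameraPR adjusted p = 0.046, 0.13 with a preset correlation of 0.05, and 0.056 with thrb left out of all lists), and glula and apoeb stood at -0.027 (SE 0.075) and -0.12 (SE 0.084) in the authors' deposited table. Adjusted over each list alone, 1 bipolar gene and 1 Müller glia gene rose, 1 horizontal gene fell, 1 amacrine gene fell and 1 rose, and 2 ganglion cell genes rose.

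Lists for other tissues and states showed no shift that passed. Adjusted p from cameraPR was 0.11 for 7 microglia and leukocyte genes (median 0.20), 0.47 for 7 endothelial genes (0.13), 0.47 for 15 immediate early and injury genes (0.030), 0.96 for 6 cell cycle genes (0.038), 0.80 for 35 circadian clock genes (-0.029) and 0.34 for 18 photoreceptor synapse genes (-0.059). Their only member past the test was per2, a light-responsive clock gene, at -0.41 (SE 0.10) in the authors' deposited table. Adjusted over each list alone, 2 immediate early genes rose and 1 fell, per2 fell, and no member of the other 4 lists passed. The most abundant members, in the authors' deposited table, were cd74a (0.23, SE 0.12) and apoc1l (0.20, SE 0.11) for leukocytes, kdr (-0.093, SE 0.11) and esama (0.15, SE 0.12) for endothelium, dusp1 (0.018, SE 0.14) and gadd45ba (-0.28, SE 0.11) for immediate early genes, ccne2 (-0.43, SE 0.18) and pcna (-0.058, SE 0.11) for the cell cycle, and cplx4a (-0.15, SE 0.093) and syt5a (-0.075, SE 0.093) for the synapse. Lens, red blood cell, skeletal muscle and keratin lists had 2, 2, 1 and 1 measured members, too few to test, and no mitochondrially encoded gene was listed under the fixed names. Their values in the authors' deposited table were 0.074 for cryabb, 0.58 for cryba4, 0.34 for cahz, -0.18 for hbaa1, -0.32 for tpma and 0.18 for krt8, with standard errors of 0.37, 0.32, 0.14, 0.30, 0.21 and 0.18. Adjusted over its list alone, cahz, a carbonic anhydrase also on the Müller glia list, rose.

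Changed genes were not spread evenly over the genome. Of the listed genes past the authors' test, mhc1uba and serinc2 lie on the chromosome that carries thrb. Leaving out thrb, that is 2 of 420 listed genes there against 4 of 8709 elsewhere (odds ratio 10.4, 95% interval 0.94 to 72.8, two-sided Fisher exact p = 0.028), a count too small to carry weight and without the unlisted genes that passed. By the test against no change, and leaving out thrb, 24 of 420 genes on that chromosome had changed (5.71%) against 165 of 8709 elsewhere (1.89%; odds ratio 3.14, interval 1.93 to 4.90, two-sided Fisher exact p = 5.61e-06). The next highest of the 25 chromosomes had 3.06%. Within 20 Mb of thrb, 21 of 331 genes had changed (odds ratio 3.48, interval 2.07 to 5.59, two-sided Fisher exact p = 4.55e-06), and 9 of 142 within 10 Mb (odds ratio 3.31, p = 0.0027 by the same test). Within 5 Mb, 3 of 56 had changed, a difference that did not pass (odds ratio 2.7, Fisher exact p = 0.11). Of the 24 genes, 13 fell and 11 rose, among them fbxl6 and fam65b. Genes on a chromosome are not independent of one another, so these p-values are too small.

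**Figure D4:**
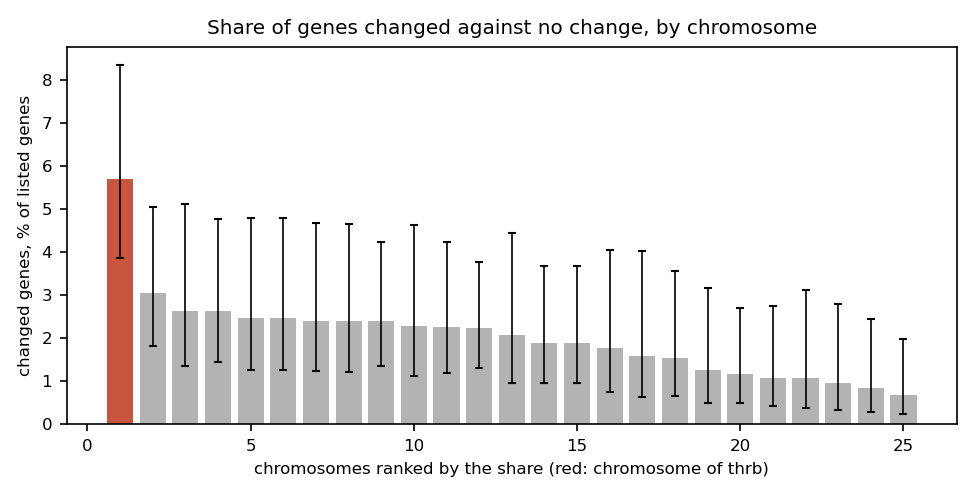
Share of listed genes that changed against no change, for each of the 25 chromosomes in descending order, with thrb left out and 95% Wilson intervals that cover counting error only. The chromosome of thrb stands highest at 5.71%, and the next one is at 3.06%.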

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

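The count of 7 listed genes changed beyond 2-fold stayed at 7 with an adjusted p under 0.1 or 0.01. It also stayed at 7 with adjustment over the listed genes, a mean count of at least 100, and centred fold changes. With a log2 fold change of at least 1 or a mean count of at least 10 it was 7 by design. The authors' test already requires a change beyond 2-fold, and the lowest mean count among the rows was 30.1. The count was 18 in a test against a 1.5-fold change and 192 against no change. Against a t distribution with 4 degrees of freedom, whose heavy tails demand a far larger statistic, it was 1 (opn1lw2). The 192 genes of the test against no change, a test chosen after seeing the data along with its alternatives, became 123 at an adjusted p under 0.01, 91 with a fold change of at least 1.5, and 1 with the t distribution. They were 166 when adjusted over 13700 genes, 268 at an adjusted p under 0.1, 194 with a mean count of at least 100, 260 with the central spread of 0.94 as the reference, and 190 after centring, which moved all fold changes by 0.003. Of 68 named genes, 41 lost their call with the t distribution and 3 when adjusted over 13700 genes (opn1sw2, adjusted p = 0.052; lhx1a, 0.055; elavl4, 0.072). With the central spread opn1sw1 (0.029) and gnao1a (0.049) gained one. No named gene reversed, but these runs leave the fold changes as they are, and centring moved them by only 0.003. They could therefore not test the direction of a named gene. The clustering of calls on the chromosome of thrb kept its direction in all runs. With thrb left out it passed over the chromosome (odds ratio 3.08 to 10.4) and within 20 Mb (3.42 to 13.4) under each setting run. Over the chromosome the 95% interval still included 1 for the authors' test (2 calls, 0.94 to 72.8). The same held for the test against no change with a log2 fold change of at least 1 (4 calls, 0.87 to 10.2). The windows of 5 and 10 Mb, with 1 to 9 calls, passed in some settings and not in others. The planned count of the authors' calls, which includes thrb, gave 15.6 over the chromosome. Of 20 tested lists, 9 passed, 6 lower and 3 higher. With thrb left out, a choice made after seeing the data, 6 of 19 passed, 4 lower and 2 higher: the thyroid list (adjusted p = 0.54) and the Müller glia list (0.056) were lost, and the red cone list was too short to test. The Müller glia list passed neither with a preset correlation of 0.05 (adjusted p = 0.13), nor ranked by log2 fold change (0.092), nor with a mean count of at least 100 (0.062). With ranks the thyroid list, tested with thrb, was lost too (0.45), and the amacrine and leukocyte lists passed upward (0.029 each). No list reversed. No paired analysis was possible because the table holds only the mean of each genotype; for the same reason no replicate could be left out and other splits of the 6 samples could not be tried, so whether a random grouping of the samples gives as many genes stays untested, and dependence on a single library is unknown. The central spread of 0.94, below the 1 of a normal distribution, gives no sign of a wider spread in the middle of the statistics. It does not describe the tails, where the calls lie. A choice between a t distribution and another model of the spread therefore needs values per sample. With the median standard error of 0.14, changes below 0.28 on the log2 scale lie within the 95% interval of a typical gene before any adjustment.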

Other observations

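The tests below were chosen only after the result was seen, except that of the odds ratio around thrb, whose prediction was written before; even there, the use of the test against no change and leaving out thrb were decided afterwards. The lists of glycolysis and protocadherin genes were also made after seeing the data.

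Some genes of glycolysis fell in the mutant retina. Of 21 measured members of a list of 35, 5 fell, none rose and 16 did not pass, with a median log2 fold change of -0.17. In the authors' deposited table pfkmb, a phosphofructokinase, had a log2 fold change of -1.03 (SE 0.15), eno3, an enolase, -0.63 (SE 0.17), tpi1a, a triosephosphate isomerase, -0.45 (SE 0.096), pkma, a pyruvate kinase, -0.30 (SE 0.086), and pgk1, a phosphoglycerate kinase, -0.29 (SE 0.088). The list as a whole ranked below other genes (cameraPR with a preset correlation of 0.01, p = 7.28e-08), and so did its 16 members that had not passed (median -0.14, cameraPR with the same preset correlation, p = 0.0078, and 0.031 with a correlation of 0.05). Neither is evidence for a fall of the pathway as such, since the list was made after falls had been seen and its 2 parts are divided by the same changes. Whether red cones carried these transcripts was not tested, and tpi1a lies on the chromosome of thrb.

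Of 18 measured genes of the clustered protocadherin 2 family, 4 rose and none fell, with a median log2 fold change of 0.39. Those that rose were pcdh2ab12, pcdh2ab11, pcdh2ab10 (0.58, SE 0.16) and pcdh2ac (0.41, SE 0.12), the last values from the authors' deposited table. The gene rassf6, separated by 1 gene from si:busm1-57f23.1 in RefSeq gene order, had a log2 fold change of -3.69 (SE 0.78) in the authors' deposited table, with means of 13.2 and 166, and passed the test against no change (Wald test adjusted p = 0.00031) but not the authors' test beyond 2-fold (adjusted p = 0.50).

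Genes changed against no change were concentrated on the chromosome of thrb. With thrb left out, their share was 5.71% over the chromosome, 6.34% within 20 Mb of thrb and 5.36% within 5 Mb. A candidate explanation is a linked block: the mutants inherit both copies of the founder chromosome around the allele, with whatever regulatory variants it holds. A block predicts a raised odds ratio within 20 Mb, and it was 3.48 (3.64 with thrb counted). That prediction was met, but the window held 331 of the chromosome's 420 genes and 21 of its 24 calls. The odds ratio therefore largely repeats the excess over the chromosome, and alone it does not show that a block is the cause. Regulation of neighbouring genes by the receptor was not tested. No value here predicts that targets of the receptor lie near thrb. With 3 calls within 5 Mb, whether the share of changed genes rises toward thrb cannot be read from these counts. Reads lost to sequence differences from the reference could also contribute: 57.1% of the 21 changed genes there fell (exact 95% interval 34.0 to 78.2), but loss in the wild-type haplotype would appear as a rise, so the mix of directions decides nothing without the sequences. A linked block, such regulation and lost reads all stay open, and mhc1uba and serinc2, which lie on this chromosome, may owe their change to their position rather than to the receptor.

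Of 8 measured pigment epithelium and melanin genes, 4 fell in the mutant and 4 did not pass. Less pigment tissue carried along with the mutant retinas may explain this, and would lower the genes of that tissue alike, but the 8 measured members differed from one another (Cochran Q against the chi-square distribution, p = 1.75e-13), with mitfb, gpr143 and trpm1b near 0. Whether those 3 are also expressed by other retinal cells, which would hide a fall, cannot be read from the table. The melanin genes dct, tyrp1b, pmela and pmelb, a subset picked after the values were seen, had a pooled log2 fold change of -0.88 (SE 0.079) without detectable difference among them (Cochran Q against the chi-square distribution, p = 0.32). Less pigment tissue and lower transcription in the pigment epithelium therefore both stay open, and visual cycle genes of that tissue, including rpe65a and stra6, are open to the same doubt; rdh5, a single gene picked for its size, fell further than the pooled melanin value by 0.88 (SE 0.23).

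Rod genes and the opsins of the other cones ranked high as a group, though only 4 of 26 passed alone and 5 lay below 0. Library scaling after the loss of red cone RNA would lift every remaining gene alike. The 26 rod and opsin genes had a median log2 fold change of 0.22 against 0.047 for 74 inner retina genes. The difference was 0.18 (two-sided permutation of genes, p = 0.00025). Genes of one cell type are not independent, so this p is too small. The sets were also compared after their list results were seen, so it is no independent test of scaling. The inner retina genes themselves ranked upward (cameraPR p = 0.021, and 0.16 with a preset correlation of 0.05). The 2 red opsins made up 0.86% of the wild-type normalized counts of the listed genes. So small a share argues against scaling from the loss of the red opsins alone, but leaves out other red cone transcripts. A general lift would also move the typical gene. The median log2 fold change over all 9211 listed genes was 0.0006, and -0.003 for those with a mean count of at least 100. For the 26 genes as a set, these values argue against scaling as the source of the rise. More rods and other cones per retina, or more transcripts per cell, stay open, since no cell counts were analysed here.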
